A study of Bos taurus with 12 samples.

How the data were processed

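Poly(A)-selected, strand-specific RNA-seq libraries were made from shoulder skin biopsies of 12 Holstein heifers, per the labels' protocols. SLICK1 is a mutation of the prolactin receptor gene PRLR that is associated with a short, sleek hair coat. The labels put 7 libraries in the genotype that carries the mutation, which the series describes as heterozygous, and 5 in the wild type. They also give each animal's age, from 46 to 79 weeks. The ages fall into 6 younger animals of 46 to 61 weeks (4 heterozygous, 2 wild type) and 6 older animals of 73 to 79 weeks (3 of each genotype). All heifers descended from 1 of 2 bulls, per the labels' protocols, but the sire of each animal is not given in the sources used here, so sire was not modelled. The labels give each library its own replicate number and an age, and no animal number. If any libraries shared an animal, the p-values would measure only the spread between these samples.

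The authors deposited whole-number read counts per gene for each library, not normalised, as 27607 Ensembl gene IDs. The submitters' processing notes name cutadapt, STAR, R 4.1.3 and the bovine genome build ARS-UCD1.2. The counting tool, the annotation release and the strand setting are not given in the sources used here. Each file ends in 5 summary lines that name no gene, and these stayed out of library sizes and tests. Alignments to no annotated gene made up 15.05% to 26.8% of all counted alignments, ambiguous ones 1.46% to 1.70%, and alignments to several places 1.97% to 3.03%. Overlapping and near-identical genes lose reads to the ambiguous and multiple classes, so their counts are uncertain. The total over gene IDs was 31312798 to 47776530 per library, and 17544 to 19874 IDs had at least 1 count.

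The files do not pair the gene IDs with symbols. The RefSeq gene table used here (assembly ARS-UCD2.0) shares no identifier with them, and 0 of the 27607 IDs matched. Results planned on named genes were therefore not run. These were PRLR, FOXA1, 25 gene lists for skin structures, cell types and pathways, and the genes near PRLR. The rule for named genes required a symbol and could not be applied. In its place, the 2 IDs per direction with the smallest unadjusted p for genotype are given, a choice made after the values were seen.

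Genes were kept with edgeR's filterByExpr by genotype (minimum count 10, minimum total 15), which left 16990. Counts were scaled by TMM (trimmed mean of M-values) and tested with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3 (glmQLFit with legacy = FALSE, then glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genotype was tested with no covariate over all 12 libraries. The age slope was tested with genotype in the model, and the genotype by age interaction in a model with both terms. These tests, the filter, the alternatives other than those named below as added, and the gene lists were fixed before the data were examined. CPM, the library-size-normalised count, used TMM-scaled library sizes, and log2 CPM used a prior count of 2. Standard errors of edgeR log2 fold changes are the absolute log2 fold change divided by the square root of F, an approximation. Intervals at 95% over all genes came from limma 3.58.1 (voom, without sample quality weights). Library measures and principal components were compared between genotypes by exact two-sided permutation tests over all 792 splits.

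The alternatives were DESeq2 1.42.0, limma voom with sample quality weights, edgeR's legacy and robust fits, other size factors and filters, age as a covariate or block, each age class alone, the replicate number as a block, and each library left out in turn. Leaving out libraries that stood apart on the principal components was added after the data were seen, as was limma voom with quality weights for age and the interaction. No pair of libraries of one genotype agreed within sampling noise: chi-square per degree of freedom was at least 69.6 over the 31 pairs. Each library counted as 1 sample. This check looked only for repeated libraries within a genotype and cannot show that 2 libraries came from different heifers. The scripts were tested on simulated data drawn from the measured means, library sizes and dispersions over 16990 genes, with the edgeR tests. Genes were drawn independently of one another, so no simulated library stood apart across many genes, and recovery in the measured libraries may be lower. For genotype, 24 of 100 genes changed 2-fold and 83 of 100 changed 4-fold were recovered, with 4 false calls. For an age change across the 33-week span, 6 of 100 were recovered at 2-fold and 55 of 100 at 4-fold, with 14 false calls. For the interaction, 0 of 100 were recovered at either size, with 0 false calls.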

Results

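Skin transcriptomes were compared between 7 heifers heterozygous for SLICK1 and 5 wild-type heifers, to find transcripts whose abundance differed with inheritance of the allele. Library depth was 40474459 ± 5479888 gene counts (SD, n = 7) in heterozygous and 37101911 ± 4594290 gene counts (SD, n = 5) in wild-type heifers. The difference did not exceed the spread between animals (exact two-sided permutation p = 0.285, adjusted p = 0.946 over 11 library measures). The number of detected gene IDs was 18785 ± 530.1 (SD, n = 7) in heterozygous and 18840 ± 914 (SD, n = 5) in wild-type skin. In each library the 10 most abundant gene IDs took between 8.10% and 18.9% of the counts. There were 20 IDs among these top 10 in at least 1 library, and 4 of them were in the top 10 of all 12 libraries.

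The largest differences between libraries did not follow genotype. The first principal component of log2 CPM held 35.0% of the variance and set apart heterozygous replicate 1 (79 weeks) and wild-type replicate 2 (75 weeks), with scores of 133.9 and 106.8 against a range of -54.9 to 36.9 in the other 10 libraries. In these libraries, 813 gene IDs were more than 4-fold above the median of the other 10 in both, and 142 were more than 4-fold below it in both. Among the 65 other pairs of libraries, the highest number shared above that limit was 160 and the median 23. For genes below it, the highest was 276 and the median 51. The pair was picked by its scores on these same values, so its high count restates the component and is not separate support. The second component held 13.3% and set apart heterozygous replicate 2 (74 weeks), with a score of 113.8. In that library 337 IDs were more than 4-fold above and 862 more than 4-fold below the median of the other 11. The number below was nearly as high in wild-type replicate 3 (846) and heterozygous replicate 1 (845). The number above was higher in heterozygous replicate 1 (1036) and wild-type replicate 2 (854). Between genotypes, the scores on the first component were 7.20 ± 61.4 (SD, n = 7) and -10.1 ± 66.0 (SD, n = 5), with an exact two-sided permutation p = 0.624. The smallest p over components 1 to 4 was 0.307, for the third (exact two-sided permutation test, adjusted p = 0.946).

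**Figure D1:**
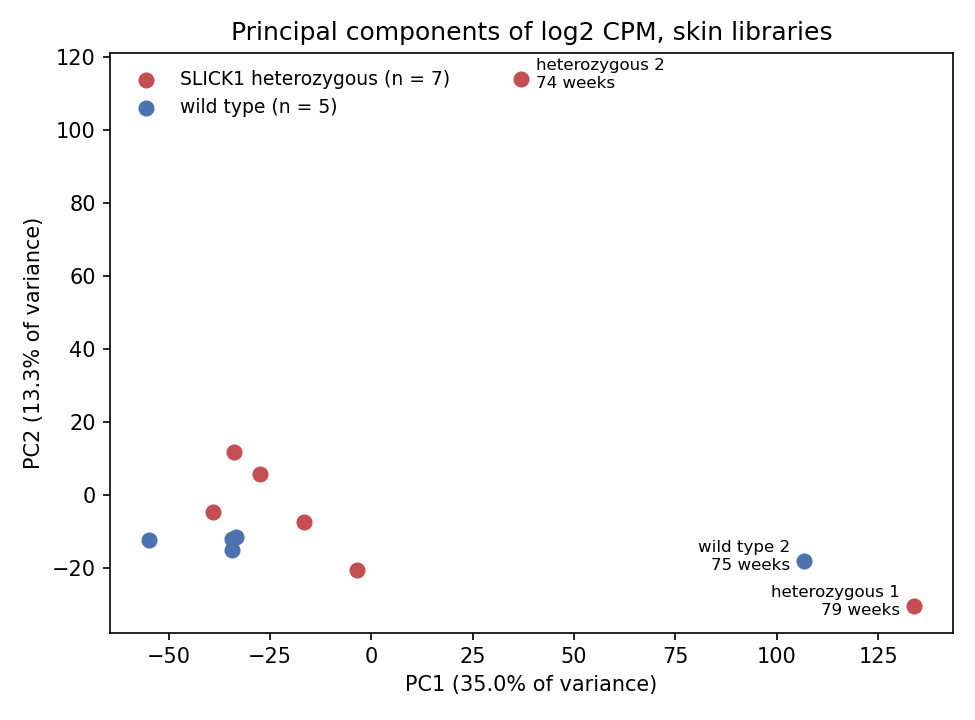
Scores of the 12 skin libraries on principal components 1 (x axis, 35.0% of variance) and 2 (y axis, 13.3%) of log2 CPM over 16990 genes, in arbitrary units; each point is 1 heifer, coloured by genotype. Heterozygous replicate 1 and wild-type replicate 2 lie far to the right and heterozygous replicate 2 lies at the top, while the other 9 libraries of both genotypes lie close together.

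No gene ID passed the test for a difference between the genotypes. Of 16990 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 0 passed 0.1. DESeq2 and limma voom with quality weights also called 0. At an unadjusted p under 0.05 there were 225 genes by edgeR, 102 higher and 123 lower in heterozygous skin. DESeq2 gave 249 and limma voom with quality weights 495, whereas 850 would be reached by uniform p-values. The median absolute log2 fold change was 0.13. The median standard deviation between animals of one genotype was 0.45 on the same scale. The median half-width of the 95% interval (limma voom) was 0.57 on the log2 scale, or 1.48-fold. That interval excluded a 2-fold difference in either direction for 11026 genes (64.9%) and a 4-fold difference for 14557 (85.7%). For the remaining genes the interval did not exclude a difference of that size. The unadjusted count rested on 2 libraries: it was 582 without heterozygous replicate 1 and 831 without wild-type replicate 2, with 0 genes past the adjusted threshold in both cases. Without both, edgeR called 0 genes, with 877 at an unadjusted p under 0.05, and DESeq2 called 6, all higher in heterozygous skin.

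The gene IDs with the smallest unadjusted p are given as values, since none passed the threshold. The IDs were not matched to symbols, so PRLR and FOXA1 were not analysed here. ENSBTAG00000017549 was at 30.7 ± 10.5 CPM (SD, n = 7) in heterozygous and 14.6 ± 3.90 CPM (SD, n = 5) in wild-type skin. Its log2 fold change was 1.07 ± 0.257 (SE; 2.11-fold). The lowest heterozygous and the highest wild-type library were both at 18.99 CPM, so the groups met at this precision. Its unadjusted p was 0.00107 by edgeR's quasi-likelihood test, which is not a permutation p, and its adjusted p was 1. ENSBTAG00000017936 was scarce, with 2 to 29 counts per library. It stood at 0.438 ± 0.208 CPM (SD, n = 7) against 0.0884 ± 0.0356 CPM (SD, n = 5), a log2 fold change of 2.23 ± 0.462 (SE), with all 7 heterozygous libraries above all wild-type libraries. In the other direction, ENSBTAG00000025792 was at 0.309 ± 0.0833 CPM (SD, n = 7) in heterozygous and 0.956 ± 0.489 CPM (SD, n = 5) in wild-type skin, a log2 fold change of -1.58 ± 0.400 (SE). Only 3 of the 7 heterozygous libraries lay below every wild-type library for this ID, which was also scarce, with 8 to 47 counts per library. ENSBTAG00000021964 was at 0.465 ± 0.215 CPM (SD, n = 7) against 1.34 ± 0.606 CPM (SD, n = 5), a log2 fold change of -1.49 ± 0.387 (SE), with 6 of 7 heterozygous libraries below every wild-type library. It had 8 to 71 counts per library. The edgeR adjusted p of each of these IDs was 1.

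**Figure D2:**
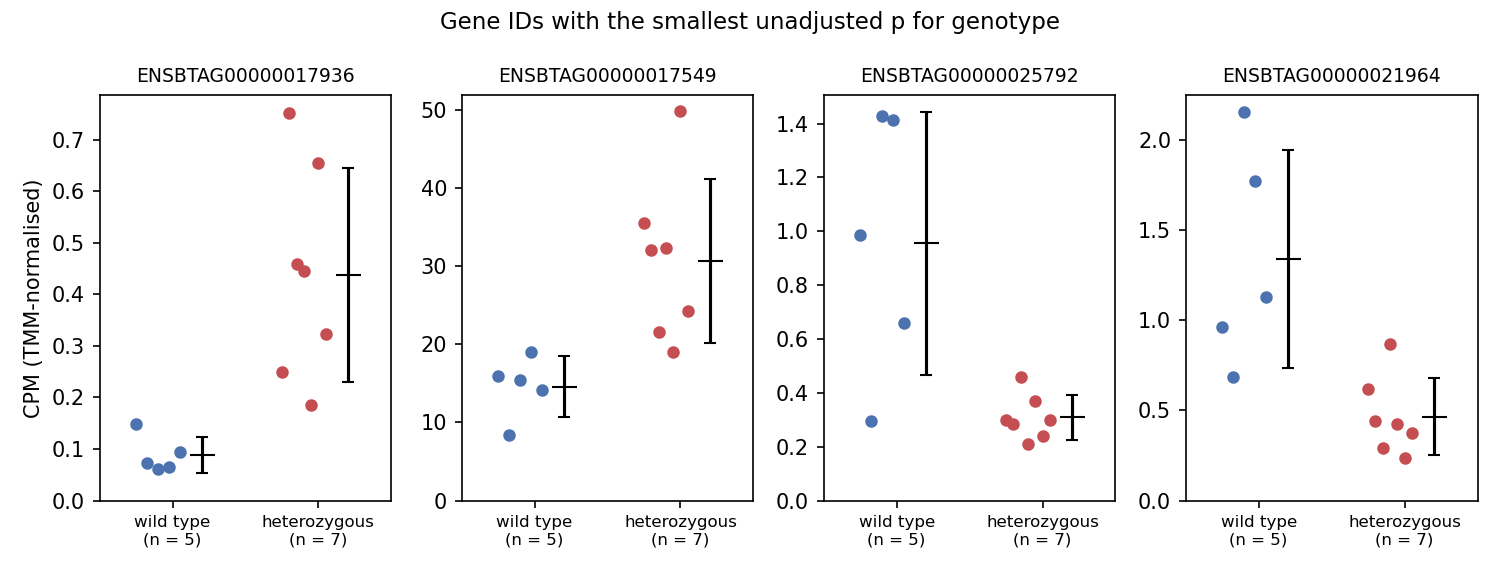
Abundance in CPM (TMM-normalised, y axis from 0, a separate scale per panel) of the 4 gene IDs with the smallest unadjusted p for genotype, 2 per direction; points are single heifers (5 wild type, 7 heterozygous) and the bars give the mean and SD. ENSBTAG00000017936 shows no overlap between genotypes, ENSBTAG00000017549 has its lowest heterozygous and highest wild-type points at the same level, ENSBTAG00000025792 and ENSBTAG00000021964 overlap, and none passed the adjusted threshold.

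The comparison was repeated within the age classes. Among the 6 older animals (3 heterozygous, 3 wild type) edgeR called 0 genes at an adjusted p of 0.05, with 269 at an unadjusted p under 0.05. Among the 6 younger animals (4 heterozygous, 2 wild type) it called 0, with 389 at an unadjusted p under 0.05. With age in weeks as a covariate, 0 genes were called and 226 had an unadjusted p under 0.05.

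Age was the other factor in the labels. With genotype in the model, edgeR called 0 of 16990 genes for an association with age (lowest adjusted p = 0.262). At an unadjusted p under 0.05 there were 2299 genes (13.5%), of which 1601 had higher and 698 lower abundance in older heifers. The median absolute change over the 33-week age span was 0.32 on the log2 scale. DESeq2 called 41 genes at an adjusted p of 0.05, with 25 higher and 16 lower in older heifers, and 2391 at an unadjusted p under 0.05. Limma voom with quality weights called 0, with 1559 at an unadjusted p under 0.05 (717 higher, 842 lower). Without heterozygous replicate 1, the oldest animal, the edgeR count at an unadjusted p under 0.05 was 1130, with 585 higher and 545 lower. Without wild-type replicate 2 as well, it was 1153 (606 higher, 547 lower); edgeR then called 0 genes and DESeq2 15. Without heterozygous replicate 2 in addition, which leaves 3 older animals, edgeR called 0 and the count was 841 (4.97% of the genes tested; 368 higher, 473 lower).

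**Figure D3:**
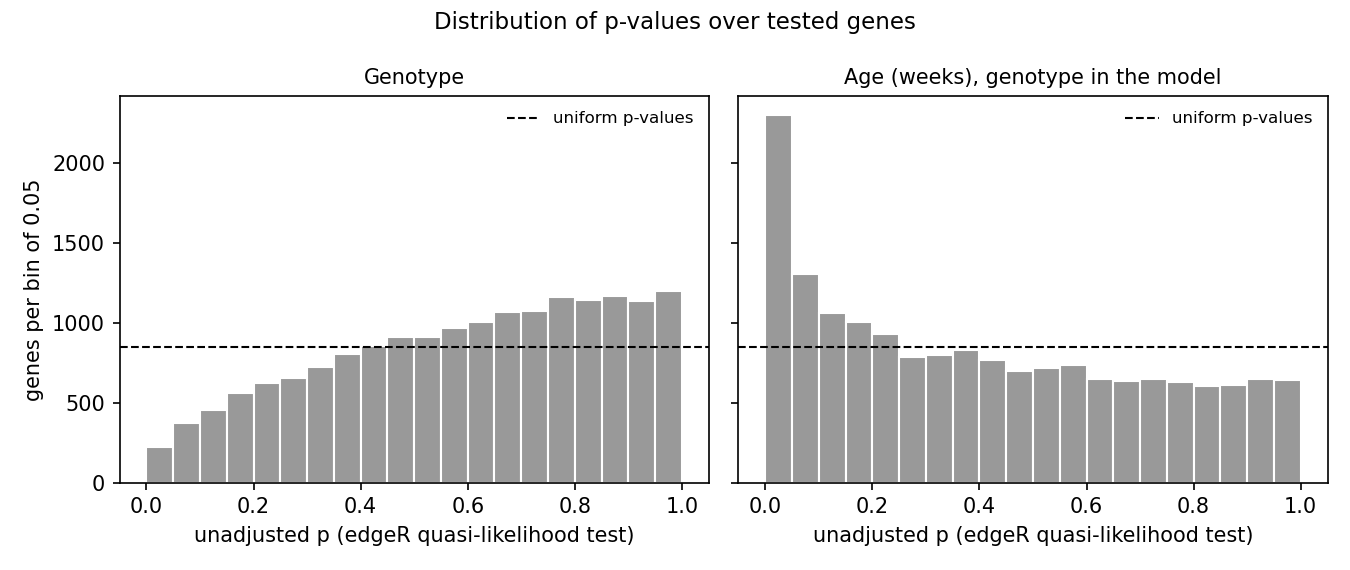
Number of genes (y axis) per bin of 0.05 of the unadjusted edgeR p-value (x axis), for genotype on the left and for age on the right, over 16990 genes; the dashed line is the height for uniform p-values. The first bin holds 225 genes for genotype and 2299 for age, against 850 for uniform p-values.

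Whether the genotype difference changed with age was tested as an interaction. EdgeR called 0 of 16990 genes, with 432 at an unadjusted p under 0.05. DESeq2 called 4 (3 with a more positive and 1 with a more negative age slope in heterozygous heifers), with 490 at an unadjusted p under 0.05, and limma voom with quality weights called 0, with 554. The edgeR count at an unadjusted p was 729 without heterozygous replicate 1, 961 without wild-type replicate 2 and 256 without heterozygous replicate 6. Without the first and second of these libraries together it was 959; edgeR then called 0 genes and DESeq2 9. In simulated data of this design, edgeR's test recovered 0 of 100 interactions of 4-fold over the age span, so its 0 calls do not exclude interactions of this size; DESeq2 was not run on simulated data.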

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

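Leaving out each library alone was planned; the tests that leave out more than 1 library were chosen after the principal components had been seen, and the count of splits at an unadjusted p was chosen after that number was known. Of 32 groups of values examined (12 library measures and the CPM of the 4 named gene IDs, 16 in each genotype), 7 held a library far from the others of its genotype. Chance flags about 1 in 20 groups, or 1.6 here, and the measures are related to one another. Wild-type replicate 2 scored 106.8 on the first principal component (other wild-type libraries -54.9 to -33.5), and its median correlation with the other libraries was 0.888 (others 0.938 to 0.953). Heterozygous replicate 1 had the lowest median correlation, 0.865 (others of its genotype 0.916 to 0.953). Heterozygous replicate 2 had 15.05% of alignments outside genes (others 21.9% to 24.6%), a TMM factor of 0.808 (others 0.982 to 1.104) and a score of 113.8 on the second component (others -30.4 to 11.9). Wild-type replicate 3 scored 86.4 on the third component (others -22.6 to 7.39).

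Fewer genes reached an unadjusted p under 0.05 for genotype than uniform p-values would give (225 of 16990, 1.32%, against 850). A test that is too strict on independent genes is argued against by simulated counts with no changed gene, of which 5.07% reached that p. In the same simulated counts 3 genes passed the adjusted threshold, all of them false calls. The libraries that stand apart on the first component, 1 of each genotype, are a candidate explanation, since they add to the spread within both groups: without both, 5.15% of genes reached that p. Leaving out wild-type replicate 2 alone gave 4.83% and heterozygous replicate 1 alone 3.45%. Each alone thus raised the share from 1.32%, the wild-type library by more. These rises overlapped, so the rise seen without both cannot be divided between the libraries. Among the 34 other pairs of 1 heterozygous and 1 wild-type library left out, those with wild-type replicate 2 gave 4.08% to 5.98%, those with heterozygous replicate 1 gave 3.68% to 5.08%, and those with neither 0.864% to 2.21%. The 3 pairs with a higher value than both libraries together all held wild-type replicate 2. In 50 other splits into groups of the same sizes, the libraries that stand apart on the first component were also in opposite groups. Their median was 444 genes at that p, below 850 but above the 225 of the real split. Having 1 such library in each group thus went with fewer genes, but does not by itself account for a count as low as 225. No biological explanation of what sets these libraries apart was tested, since their genes carry no names here.

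More genes reached an unadjusted p under 0.05 for age than uniform p-values would give (2299, 13.5%). The libraries that stand apart on the first component both come from older animals, and without them the share was 6.77%, between the values that would have argued for and against them as the whole cause. Without heterozygous replicate 2 as well, also from an older animal, it was 4.97%, with 368 genes higher and 473 lower in older heifers (1601 and 698 with all libraries), so neither the excess nor its direction remained. As 3 of the 6 older animals are then left out, this does not tell those libraries from a loss of older animals. Leaving out heterozygous replicate 1 alone, the oldest animal, already gave 6.7% (585 higher, 545 lower). Leaving out wild-type replicate 2 alone gave 9.01% (1070 higher, 481 lower). Without heterozygous replicate 2 alone the share stayed at 13.6% (1739 higher, 560 lower). Of 100 orders of the ages, the real one included, 9 gave as many genes, and the highest other order gave 4594. A chance order of the ages can therefore not be excluded. An effect of age itself stays open.

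The 0 genes called for genotype were also set against other splits of the 12 libraries into 7 and 5. With 0 genes in the real split, every split gives as many (100 of 100), so this count decides nothing about chance. Of the splits, 7 called any gene, and the highest other split called 508. That split placed both libraries that stand apart on the first component in the group of 5. These libraries were picked from the same values, so this restates the first component and is not separate support for a structure of the samples. At an unadjusted p under 0.05, 99 of the 100 splits gave at least the 225 genes of the real one, and the highest other gave 3431. Splits with both of these libraries in one group gave a median of 1420 genes, and splits that separated them gave 444.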

How the results depend on the processing

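The count of 0 genes for genotype held under 28 of 29 alternatives, among them each library left out in turn, and each ID named kept its direction and an adjusted p above 0.05 wherever it was tested. The exception was DESeq2 without the 2 libraries that stand apart on the first component (added after seeing the data), which called 6 genes, all higher in heterozygous skin; edgeR called 0 on the same libraries. The number at an unadjusted p under 0.05 was 225 (1.32% of 16990 tested) in the main fit. It moved to 404 (1.79% of 22530) with no filter on low counts and 141 (0.949% of 14863) with CPM over 1 in 5 samples. Without those 2 libraries it was 877 (5.15% of 17025), and 704 (4.16% of 16907) without heterozygous replicate 2 as well. The named IDs were chosen by the smallest p in these same data, so their kept direction is not separate support. Of them, only ENSBTAG00000017549 passed the filter of CPM over 1 in 5 samples. For age, 19 of 21 alternatives kept 0 genes; DESeq2 called 41, and 15 without the 2 libraries, of which 3 were shared with the 41. For the interaction, 19 of 21 kept 0; DESeq2 called 4, and 9 without the 2 libraries. The cause of these differences between tools was not tested. With the replicate number as a block (numbers 1 to 5, 10 libraries), 0 genes were called for genotype and 281 had an unadjusted p under 0.05. The numbers were not taken to pair animals. Deviations of same-numbered libraries correlated between -0.222 and 0.321 across genes, over 0.1 in 4 of 5 pairs. The mean over pairs with different numbers was -0.00991. Of the wild-type libraries, 2 of 5 correlated best with their own number. Within each genotype the numbers run from older to younger heifers, so same-numbered libraries also shared an age class. Alternatives for PRLR, FOXA1, the gene lists and the PRLR region were not run, since the gene IDs matched no symbol. Depth limits scarce genes such as ENSBTAG00000017936, with 2 to 29 counts per library. At the depth and animal numbers of this design, edgeR recovered 24 of 100 simulated 2-fold genotype changes. The simulated genes were independent, with no library set apart across many genes, so recovery in the measured libraries may be lower.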

Other observations

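For 8 genes the 7 heterozygous and 5 wild-type libraries did not overlap in log2 CPM, however small the gap, 2 with higher and 6 with lower values in heterozygous skin. Chance gives 0.253% of genes, or 42.9 of 16990, if genes were independent. Among all 792 splits of the libraries, 764 gave at least 8 such genes, the median split gave 31 and the highest other 435. The number of separated genes therefore gave no sign of a genotype difference beyond chance.

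A genotype effect on many genes would be expected to recur in separate animals. The log2 differences between genotypes in the 6 older and the 6 younger heifers had a Pearson correlation of 0.0746 and a Spearman correlation of -0.00499 across 16990 genes, which are not independent replicates. Of the 300 relabelings of genotype within the age classes, 79 gave a Pearson correlation as high (exact one-sided permutation p = 0.263), and 95% of them lay between -0.192 and 0.192. A shared pattern was thus not shown, and it is not excluded, since the power of this comparison was not measured. The older class held all 3 libraries set apart on the first or second component. The younger class held only 2 wild-type heifers.

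The share of alignments outside annotated genes was 21.7% ± 3.05 (SD, n = 7) in heterozygous and 21.8% ± 3.001 (SD, n = 5) in wild-type skin, a difference smaller than the spread between animals (exact two-sided permutation p = 0.946).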
